A study of Rattus norvegicus with 16 samples.

How the data were processed

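RNA of isolated rat pancreatic islets was measured on a rat oligonucleotide expression array in a 2 by 2 design. Per the labels, islets received an empty (null) adenovirus or an adenovirus carrying PPARγ (the nuclear receptor peroxisome proliferator-activated receptor gamma) at 50 viral particles per cell for 32 h, and then spent 16 h in vehicle (0.004% DMSO) or in 200 nM GW347845, a PPARγ agonist. The table had 16 columns, 4 per group, and every column was assigned by its label alone. The labels do not say whether replicates were separate islet preparations, separate cultures or repeated arrays of the same RNA, so the replicates may be technical. The species of the viral PPARγ cDNA, the software that summarised the probes and the genome build are not given in the sources used here.

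The deposited values are in intensity, 1 value for each of 15923 probe sets, on a linear scale and without detection calls. The authors had scaled each array: after trimming 2% at each end, the mean was 150.0 in every column, and medians lay between 56.4 and 67.5. By a rule set beforehand, values were therefore used as deposited, without further normalization between arrays. An array gives no count of molecules, so no depth is stated, and the number of arrays limits the precision.

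The columns of null virus vehicle replicate 2 and null virus compound replicate 2 held the same value in all 15923 probe sets, while no other pair of columns was identical in more than 0.936% of them. The same array had thus been deposited under 2 conflicting labels. Both columns were left out, before any comparison was looked at, which left 14 arrays: 3 in each null virus group (replicates 1, 3 and 4) and 4 in each PPARγ virus group. The design had been written for all 16 columns. Fits with all 16 columns, and with the array kept under either label, were run as alternatives.

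Values were taken as log2(value + 4.6), where 4.6 is the 10th percentile of all positive values. Fold changes are on this scale and understate the change of genes with low intensity. A probe set was tested if its intensity was above 39.3, the 40th percentile of the table, in at least 4 arrays; 57 control probe sets were not tested. This left 10078 probe sets, of which 8488 named 1 gene, 235 named several and 1355 named none. Gene symbols came from the platform's own annotation and were updated through a current rat gene table by gene identifier; positions on the genome were not used here.

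A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend on mean intensity). It gave 6 contrasts: the virus effect in vehicle and in compound, the compound effect under each virus, the combined effect (PPARγ virus with compound against null virus with vehicle) and the interaction. The Benjamini-Hochberg adjustment ran over all tested probe sets of a contrast, with a threshold of 0.05. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

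Genes were named by a rule fixed before the data were examined, as were the gene lists, the contrasts and most alternatives. In each of the vehicle virus contrast, the compound contrasts and the combined contrast, the rule took Pparg, up to 8 rises and 8 falls past the threshold whose arrays did not overlap between groups, and up to 3 passing members of each gene list by smallest adjusted p. Where fewer than 5 probe sets passed, it took the 5 rising and 5 falling genes with the smallest p, given as values that did not pass. For the interaction, it took up to 8 passing probe sets in each direction by smallest adjusted p; none passed, so the 5 and 5 with the smallest p are given there as well. The rule leaves out probe sets of several genes or of none. List members that passed adjusted over the list alone are given by name only in part. Other genes outside the rule were chosen after their values were seen and are stated to be so.

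The 18 gene lists were PPARγ target and adipocyte lipid handling genes, fatty acid oxidation and peroxisome, fatty acid synthesis and desaturation, cholesterol synthesis and uptake, beta cell identity and glucose sensing, secretory granule and exocytosis, non-beta islet hormones, inflammatory response, interferon response and antigen presentation, endoplasmic reticulum stress, glycolysis, citrate cycle and respiratory chain, cell cycle, immediate early and heat shock genes, and markers of acinar, duct, endothelial and stromal, and leukocyte cells. A list gene was represented by its probe set with the highest mean. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists of a contrast. Camera with an estimated correlation and the rotation test fry were run beside it. Member counts are given over all probe sets and adjusted over the list alone.

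Whether replicate numbers pair arrays was checked on deviations from the group mean. Within each virus, vehicle and compound arrays of the same number correlated (r across probe sets 0.445 to 0.475 under the null virus and 0.574 to 0.702 under the PPARγ virus), above the highest value of other numbers (-0.197 and 0.329). Across viruses the same number did not pair arrays throughout (-0.120 to 0.433 in vehicle and -0.0216 to 0.302 in compound). Number 1 arrays correlated (0.433 in vehicle and 0.302 in compound), while numbers 3 and 4 stood at -0.120 and 0.120 in vehicle. In compound numbers 3 and 4 stood at -0.00547 and -0.0216. A replicate block within each virus was therefore added for the compound contrasts and the interaction, and its calls and list counts stand beside them.

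The model was tested on simulated data of the same group sizes without paired arrays. A change of 2-fold was recovered for 75% to 85% of 100 simulated probe sets, depending on the contrast. For a change of 4-fold it was 96% to 99%. In each simulation 100 probe sets of each size changed at once, which eases the adjusted threshold. Recovery was not measured where few probe sets change and would be lower there. False calls were at most 14 of 194 calls. Simulated lists of 26 probe sets shifted by 0.4 on the log2 scale were each called, and 0 of the other lists were. The simulated probe sets were drawn independently of one another. The simulation therefore cannot show how often camera calls a list falsely where its genes correlate.

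Pparg intensity and array quality were also compared with exact two-sided permutation tests, and quality also by exact sign changes within pairs, a test added after the pairing was known. Alternatives were quantile normalization, median centring, other pseudocounts, no filter and a stricter filter, eBayes without trend, array weights, only the groups compared, a replicate block, other thresholds, all probe sets of a gene averaged, and leaving out each array in turn. The fits with the doubly labelled array, the block within each virus, the use of numbers 1, 3 and 4 alone, and a comparison of virus effects between arrays of other numbers were chosen after the data had been seen.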

Results

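The series measured gene expression in rat pancreatic islets that received a null adenovirus or a PPARγ adenovirus and then vehicle or the PPARγ agonist GW347845 at 200 nM for 16 h. The comparisons rest on 14 arrays: 3 of null virus with vehicle, 3 of null virus with compound, 4 of PPARγ virus with vehicle and 4 of PPARγ virus with compound. A further array, deposited with the same values under both null virus labels, was left out. Median intensity per array was 56.4 to 67.5. The ratio of 3 prime to 5 prime signal, a measure of RNA integrity, was 8.36 to 18.9 for the Gapdh controls and 7.58 to 14.9 for the beta-actin controls. The Gapdh ratio of 18.9 was that of null virus compound replicate 3 alone. The next highest was 12.6, in PPARγ virus vehicle replicate 1. Between groups, without pairing, no exact permutation test of these measures gave a p under 0.05; with 3 arrays against 4 the smallest p possible was 0.0571. In pairs of the same virus and number, the beta-actin ratio was higher with compound in 7 of 7, by 0.30 on the log2 scale (exact two-sided permutation p = 0.0156, the smallest possible, and 0.0469 adjusted over 3 measures). The Gapdh ratio was higher in 4 of 7 (exact p = 0.672).

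The virus contrast in vehicle asked what the receptor does without added ligand. Pparg itself read 33.0 ± 5.74 (SD, n = 3) intensity with the null virus and 5593 ± 582 (SD, n = 4) with the PPARγ virus, a 149-fold rise (log2 change 7.22 ± 0.18 SE, adjusted p = 3.35e-12). Plek, which encodes pleckstrin, a protein kinase C substrate of platelets and leukocytes, rose 6.26-fold (2.65 ± 0.31, adjusted p = 0.00237). Gpd1, the glycerol-3-phosphate dehydrogenase that supplies glycerol phosphate for triglyceride, rose 3.90-fold (1.97 ± 0.24, adjusted p = 0.00268), from 73.2 ± 11.4 (SD, n = 3) to 312 ± 108 (SD, n = 4). The kinase gene Sgk2 rose 2.01-fold (1.01 ± 0.16, adjusted p = 0.0342). Every array of the PPARγ virus was above every null virus array for these 4 genes, a condition of the naming rule for rises.

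In the fit without a block, these 4 rises and 0 falls were all the calls limma made among 10078 probe sets. At an unadjusted level, 446 probe sets had a p under 0.05, where chance alone gives 503.9. For Pparg the exact permutation p was 0.0571, the smallest possible. Genes with the next smallest p did not pass. Among them were the triglyceride synthesis gene Dgat2 (0.96, adjusted p = 0.0731), the lipid droplet coat gene Plin2 (0.93, adjusted p = 0.114), Litaf (0.66), Hmox2 (0.65) and Fga (1.27). On the falling side stood Stard3nl (-0.68, adjusted p = 0.0731), Calml4 (-0.74), the clock gene Cry2 (-0.93), the chemokine gene Cxcl10 (-0.70) and Ndufa7 (-0.49).

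As a group, PPARγ target and adipocyte lipid handling genes rose with the virus alone. Their mean log2 change was 0.39 (camera adjusted p = 1.59e-08, and 0.0433 with an estimated correlation). Of 26 measured members, 1 (Gpd1) rose over all probe sets. Adjusted over the list alone, 7 rose, with Fabp4, Angptl4, G0s2, Plin2, Dgat2 and Nr1h3 added. Fatty acid oxidation genes had a mean change of 0.20 (camera adjusted p = 1.98e-05, but adjusted p = 0.0818 with an estimated correlation). Over all probe sets 0 of 27 passed, and 3 (Acadl, Acadvl, Ehhadh) passed adjusted over the list alone. Interferon response and antigen presentation genes had a mean of -0.25 (camera adjusted p = 1.99e-06, but adjusted p = 0.0738 with an estimated correlation). Of these 27 genes, 0 passed over all probe sets and 1, the immunoproteasome gene Psmb9 (-0.56), adjusted over the list alone. Duct cell markers had a mean of 0.22 (camera adjusted p = 0.00169, but adjusted p = 0.0864 with an estimated correlation), with 0 of 9 passing either way. Inflammatory genes had a mean of -0.21 (camera adjusted p = 0.00608, but adjusted p = 0.565 with an estimated correlation). Of these 24 genes, 0 passed over all probe sets and 1 (Cxcl10) adjusted over the list alone. Cell cycle genes had a mean of -0.15, with 0 of 26 passing either way (camera adjusted p = 0.0194; adjusted p = 0.576 with an estimated correlation).

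Fitted on the groups compared alone, the contrast made 1 call, with Plek at an adjusted p of 0.115 and Gpd1 at 0.0721. A replicate block over all groups, although not every number paired arrays across viruses, gave 34 calls (22 up, 12 down). The count was 7 without PPARγ virus vehicle replicate 3 or PPARγ virus compound replicate 2. Sgk2 was lost in 11 of the 14 fits that left out 1 array (adjusted p to 0.214), all but those without null virus compound replicate 1 or 4 or PPARγ virus compound replicate 2. The inflammatory call ended without null virus vehicle replicate 1 (adjusted p = 0.0549), and without a filter. The cell cycle call ended without null virus vehicle replicate 1 (0.0523) or 4 (0.371, mean -0.07) or PPARγ virus vehicle replicate 2 (0.190, mean -0.08). It also ended with the replicate block over all groups, with all 16 columns and with the doubly labelled array as null virus vehicle.

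**Figure D1:**
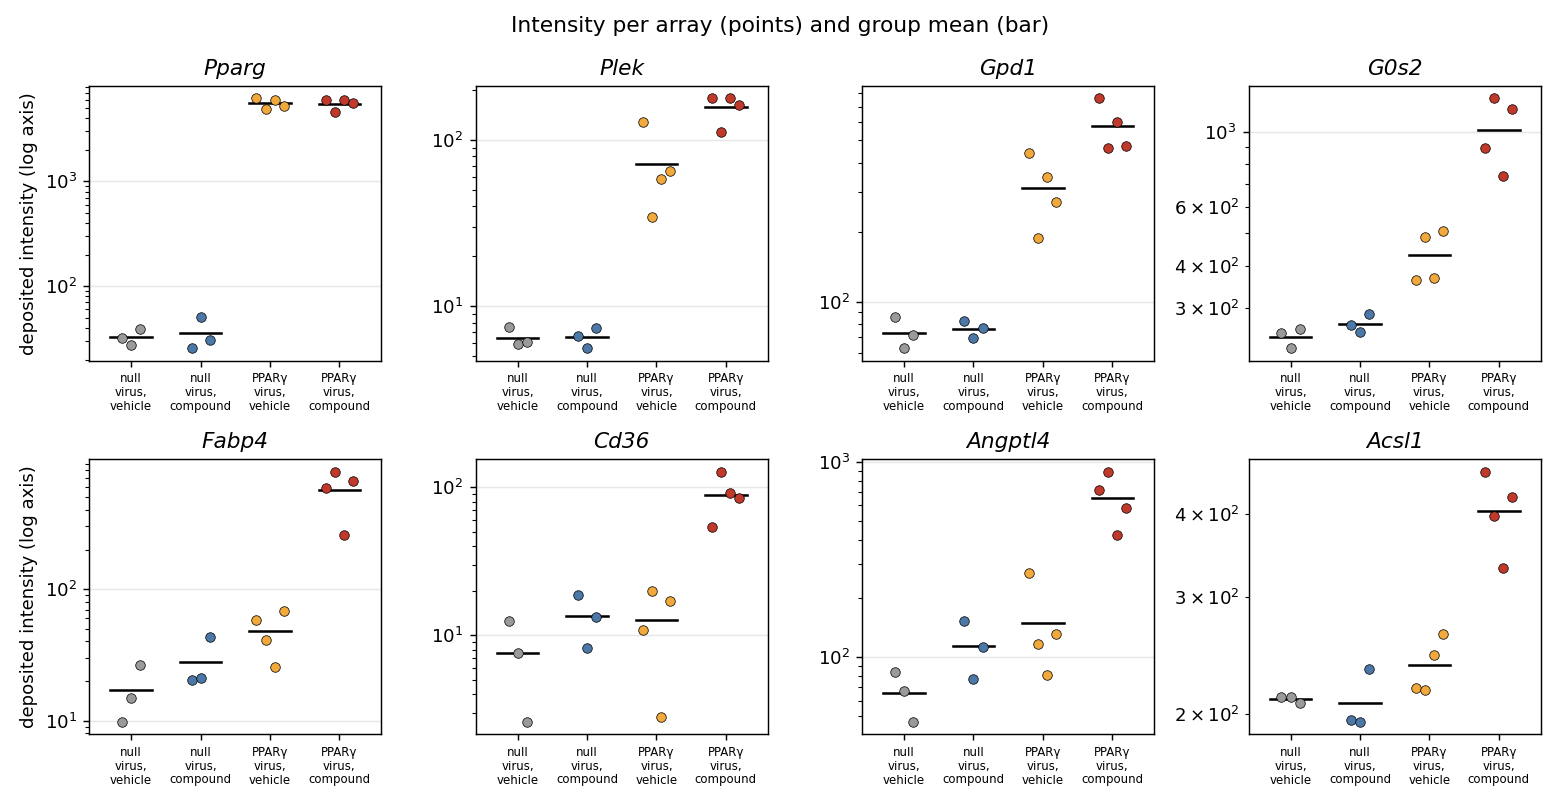
Intensity (log axis) of 8 genes in each of the 14 arrays, by group; points are arrays and bars are group means. Pparg was near 5593 and 5510 with the PPARγ virus and near 33.0 and 35.8 with the null virus. The group means of Plek, Gpd1, G0s2, Fabp4, Cd36, Angptl4 and Acsl1 were highest where the PPARγ virus and the compound were combined.

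The compound contrast under the null virus asked what GW347845 does at the islets' own receptor level. No gene passed the test. Fabp4, the adipocyte fatty acid-binding protein, read 17.0 ± 8.45 (SD, n = 3) in vehicle and 28.1 ± 12.9 (SD, n = 3) in compound; its log2 change was 0.60 ± 0.42 (adjusted p = 1.00). The secreted lipase inhibitor gene Angptl4 stood at 0.74 ± 0.38 and the fatty acid transporter gene Cd36 at 0.61 ± 0.46, while a further probe set annotated to both Cd36 and Cd36l1 stood at 0.73 ± 0.21 (adjusted p = 1.00). These genes lie outside the naming rule in this contrast and were chosen after their values were seen. PPARγ target genes as a list had a mean log2 change of 0.06, with 0 of 26 passing over all probe sets or adjusted over the list alone (camera adjusted p = 0.984). Its mean and median were positive, while camera, which sets the list's test statistics against those of other genes, placed it down. Pparg was at 0.06 ± 0.19. The beta-actin ratio was higher with compound in 3 of 3 pairs, by 0.38.

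Limma called 0 probe sets here, with 95 at an unadjusted p under 0.05, where chance alone gives 503.9. The replicate block within each virus also gave 0 calls, with 411. Without the block the fit ignores that arrays of a number deviate together, which makes its compound tests conservative. The median 95% confidence interval of a log2 change reached 0.39 to either side. The same model recovered 75% of simulated 2-fold changes where 100 probe sets of each size changed at once. That share overstates what would be found if few probe sets changed. The genes with the smallest p on the rising side were Pik3ap1 (0.60), Stub1 (0.44), Eid1 (0.58), Borcs8 (0.44) and Mindy1 (0.56). On the falling side they were Xylt2 (-0.50), Plcg1 (-0.48), Ppp6r1 (-0.42), Capn8 (-0.55) and Sec31a (-0.72), each at an adjusted p of 1.00. No list passed camera without the block; with it, cell cycle genes did (mean 0.09, adjusted p = 0.0208; adjusted p = 0.761 with an estimated correlation). Adjusted over the list alone, the block gave 1 falling member in the lists tested, an interferon response gene.

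The compound contrast under the PPARγ virus asked the same where the receptor was abundant. Members of the PPARγ target and adipocyte lipid handling list rose. Fabp4 went from 48.2 ± 18.7 to 572 ± 223 intensity (SD, n = 4 each), a 10.7-fold rise (log2 change 3.42 ± 0.36 SE, adjusted p = 0.000737). Cd36 rose 5.73-fold (2.52 ± 0.39, adjusted p = 0.0242), from 12.65 ± 7.59, under the 39.3 used as the lower limit for testing, to 89.05 ± 30.04 (SD, n = 4 each). Angptl4 rose 4.51-fold (2.17 ± 0.33, adjusted p = 0.0220), and G0s2, an inhibitor of adipose triglyceride lipase, rose 2.31-fold (1.21 ± 0.16, adjusted p = 0.00817). Acsl1, which activates fatty acids to acyl-CoA, rose 1.69-fold (0.76 ± 0.12, adjusted p = 0.0242); its other probe set gave 0.74 and did not pass. All 5 genes were higher in each of the 4 compound arrays than in any of the 4 vehicle arrays, a condition of the naming rule for rises. Pparg stood at -0.02 ± 0.17 (adjusted p = 1.00, exact permutation p = 0.886). The beta-actin ratio was higher with compound in 4 of 4 pairs, by 0.24.

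With the probe set annotated to both Cd36 and Cd36l1 (1.92, adjusted p = 2.49e-04), which the naming rule leaves out, these were the 6 calls, 6 rises and 0 falls. An unadjusted p under 0.05 was found for 295 probe sets, where chance alone gives 503.9. The named genes all belong to the PPARγ target list, whose mean change was 0.70 (camera adjusted p = 1.45e-31, and 2.45e-04 with an estimated correlation). Of its 26 members, 5 rose over all probe sets and 12 adjusted over the list alone, with Lpl, Gpd1, Dgat2, Plin2, Pck1, Nr1h3 and Aqp7 added. Fatty acid oxidation genes rose as a list by 0.23 on average (camera adjusted p = 3.74e-09, and 0.0221 with an estimated correlation). Single members passed in 0 of 27 cases over all probe sets and in 5 (Pex11a, Ehhadh, Decr1, Eci2, Etfdh) adjusted over the list alone. Leukocyte markers had a mean of -0.16, with 0 of 15 passing either way (camera adjusted p = 0.0381; adjusted p = 0.864 with an estimated correlation). Citrate cycle and respiratory chain genes had a mean of 0.05, with 0 of 36 passing either way (camera adjusted p = 0.0381; adjusted p = 0.864 with an estimated correlation).

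With the replicate block within each virus, 40 probe sets passed (36 up, 4 down), all 6 of the above among them. The examples here were picked after their values had been seen. The glutathione transferase genes Gsta4 (2.13, adjusted p = 2.83e-04 with the block) and Mgst1 (0.95, adjusted p = 5.71e-04) rose. So did the growth factor gene Igf1 (2.19, adjusted p = 0.0101), the lipoprotein lipase gene Lpl (1.15, adjusted p = 0.00995), Gpd1 (0.91), Dgat2 (0.72), the peroxisome proliferation gene Pex11a (0.90) and the mitochondrial beta-oxidation gene Decr1 (0.51). The 4 falls were Vash1 (-0.44), Arhgef28 (-0.78), Bclaf1 (-0.37) and a probe set that names no gene (-1.68). Among PPARγ target genes, 9 of 26 rose over all probe sets and 18 adjusted over the list alone with the block (camera adjusted p = 2.01e-24, and 0.00191 with an estimated correlation). Among fatty acid oxidation genes, 3 of 27 rose over all probe sets and 9 adjusted over the list alone (camera adjusted p = 9.95e-09, and 0.00914 with an estimated correlation). Leukocyte markers had 0 of 15 passing over all probe sets and 2 falling adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.255 with an estimated correlation). Citrate cycle genes had 0 of 36 passing either way (camera adjusted p = 0.0192; adjusted p = 0.612 with an estimated correlation). Cell cycle genes also passed camera with the block (mean 0.08, adjusted p = 0.0177; adjusted p = 0.446 with an estimated correlation), with 0 of 26 passing either way. Lists that did not pass camera had members that passed adjusted over the list alone: 4 inflammatory, 2 duct and 1 non-beta hormone gene rose, and of fatty acid synthesis genes 1 rose and 1 fell.

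Without the block, leaving out PPARγ virus vehicle replicate 3 or PPARγ virus compound replicate 4 left 2 calls, leaving out PPARγ virus compound replicate 1 or 2 left 3, and a fit on the groups compared alone made 2. Fabp4 passed in every fit. G0s2 was lost without vehicle replicate 3 (adjusted p = 0.0502) or compound replicate 4 (0.0516). Cd36 was lost without vehicle replicate 1 (0.0759) or 3 (0.0623), and was untested for low intensity in 4 further fits. Angptl4 was lost without vehicle replicate 2, 3 or 4 or compound replicate 1, 2 or 4 (to 0.0956), and Acsl1 without vehicle replicate 1, 2 or 3 or compound replicate 1, 2 or 4 (to 0.119). The leukocyte call ended without replicate 4 of either null virus group, vehicle replicate 1 (0.546) or 4, or compound replicate 2, 3 or 4; its mean was -0.01 without vehicle replicate 1 and -0.10 without compound replicate 3. The citrate cycle call ended without replicate 4 of either null virus group, vehicle replicate 1 or 2, or compound replicate 3 or 4. Its mean was 0.02 without vehicle replicate 1 or 2 and -0.01 (adjusted p = 0.890) without compound replicate 4.

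The combined contrast set islets with both receptor and agonist against the double control. Fabp4 rose 26.02-fold (log2 change 4.70 ± 0.39 SE, adjusted p = 1.29e-05), Plek 14.5-fold (3.86 ± 0.31, adjusted p = 1.25e-05) and Gpd1 7.35-fold (2.88 ± 0.24, adjusted p = 1.29e-05). Gsta4, a glutathione transferase that clears lipid peroxidation products, rose 11.7-fold (3.55 ± 0.46, adjusted p = 0.00142), from 29.9 ± 15.1 (SD, n = 3) to 422 ± 219 (SD, n = 4). Angptl4 rose 9.22-fold (3.20), Cd36 7.85-fold (2.97), G0s2 3.96-fold (1.99) and Igf1 6.75-fold (2.75). The other Igf1 probe set stood at 0.58 and did not pass. Pparg rose 147-fold (7.20 ± 0.18). Falls were smaller: Calml4, a calmodulin-like gene, fell by 0.92 (adjusted p = 0.00901), Psmb9 by 0.72 (0.0306), the dynactin gene Actr10 by 0.69 (0.0366), Stard3nl by 0.64 (0.0176) and Bclaf1 by 0.59 (0.0276). The other probe sets of Actr10 (-0.12) and Bclaf1 (-0.08) did not pass.

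In all, 67 probe sets passed, 61 up and 6 down, at 855 with an unadjusted p under 0.05. Of the 26 PPARγ target genes, 10 rose over all probe sets and 16 adjusted over the list alone, with a mean change of 1.09 (camera adjusted p = 7.66e-27, and 5.01e-04 with an estimated correlation). Fatty acid oxidation genes rose by 0.44 on average, 7 of 27 over all probe sets and 10 adjusted over the list alone (camera adjusted p = 2.26e-11, and 0.0102 with an estimated correlation). They included Pex11a (1.34, adjusted p = 0.00137), the peroxisomal bifunctional enzyme gene Ehhadh (2.32, adjusted p = 0.00284) and Decr1 (0.79, adjusted p = 0.00384), with Acadl, Acadvl, Acaa2 and Etfdh. Fatty acid synthesis genes did not pass as a list (mean -0.11, camera adjusted p = 0.277), and 1 of 15, the elongase gene Elovl5 (0.52, adjusted p = 0.0295), rose over all probe sets and adjusted over the list alone.

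Among cell type markers, duct genes had a mean change of 0.28 (camera adjusted p = 0.00490, but adjusted p = 0.128 with an estimated correlation). The keratin gene Krt19 (1.30, adjusted p = 0.0391) was the 1 of 9 to rise over all probe sets, and 4 rose adjusted over the list alone. Interferon response genes had a mean of -0.27 (camera adjusted p = 8.40e-05, but adjusted p = 0.122 with an estimated correlation). Psmb9 was the 1 of 27 to fall, over all probe sets and adjusted over the list alone. Beta cell genes had a mean of -0.19 (camera adjusted p = 0.0188, but adjusted p = 0.753 with an estimated correlation). Of these 20 genes, 0 passed over all probe sets and 2 adjusted over the list alone, the transcription factor gene Pdx1 (-0.67) and the gap junction gene Gjd2 (-0.95). The insulin genes Ins1 and Ins2, which lie outside the naming rule and were chosen after their values were seen, stood at -0.09 and -0.04. Glycolysis genes had a mean of 0.17, with 0 of 21 passing either way (camera adjusted p = 0.0188; adjusted p = 0.510 with an estimated correlation).

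The remaining lists did not pass camera in the combined contrast. Their mean log2 changes were 0.13 for cholesterol synthesis, -0.12 for secretory granule genes, -0.16 for non-beta islet hormones, 0.27 for acinar markers, -0.01 for endothelial and stromal markers, and -0.11 for leukocyte markers. For inflammatory genes the mean was -0.11, with 0.05 for endoplasmic reticulum stress, 1.46e-04 for the citrate cycle and respiratory chain, -0.07 for the cell cycle and -0.01 for immediate early and heat shock genes. For the last of these, mean and median were negative while camera's direction was up. Over all probe sets 0 members of these lists passed. Adjusted over the list alone, 1 endothelial and stromal gene (Plvap, 1.59), 1 inflammatory gene (Cx3cl1, 1.81) and 1 respiratory chain gene (Cox4i1, 0.41) rose. Acinar marker scores, the mean deviation of 9 genes on the log2 scale, ranged from -0.61 in PPARγ virus vehicle replicate 4 to 0.80 in null virus compound replicate 1. These transcripts thus varied within groups, and in part by number across both viruses. Acinar scores were 0.72 to 0.80 in the number 1 arrays and -0.61 to -0.43 in the number 4 arrays. In the number 3 arrays they spread from -0.59 to 0.02. Scores of the non-beta islet hormone list varied more, from -1.43 in PPARγ virus compound replicate 2 to 0.88 in PPARγ virus vehicle replicate 3. Under the PPARγ virus they were above 0 in numbers 1 and 3 and below 0 in numbers 2 and 4, in vehicle and in compound alike.

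**Figure D2:**
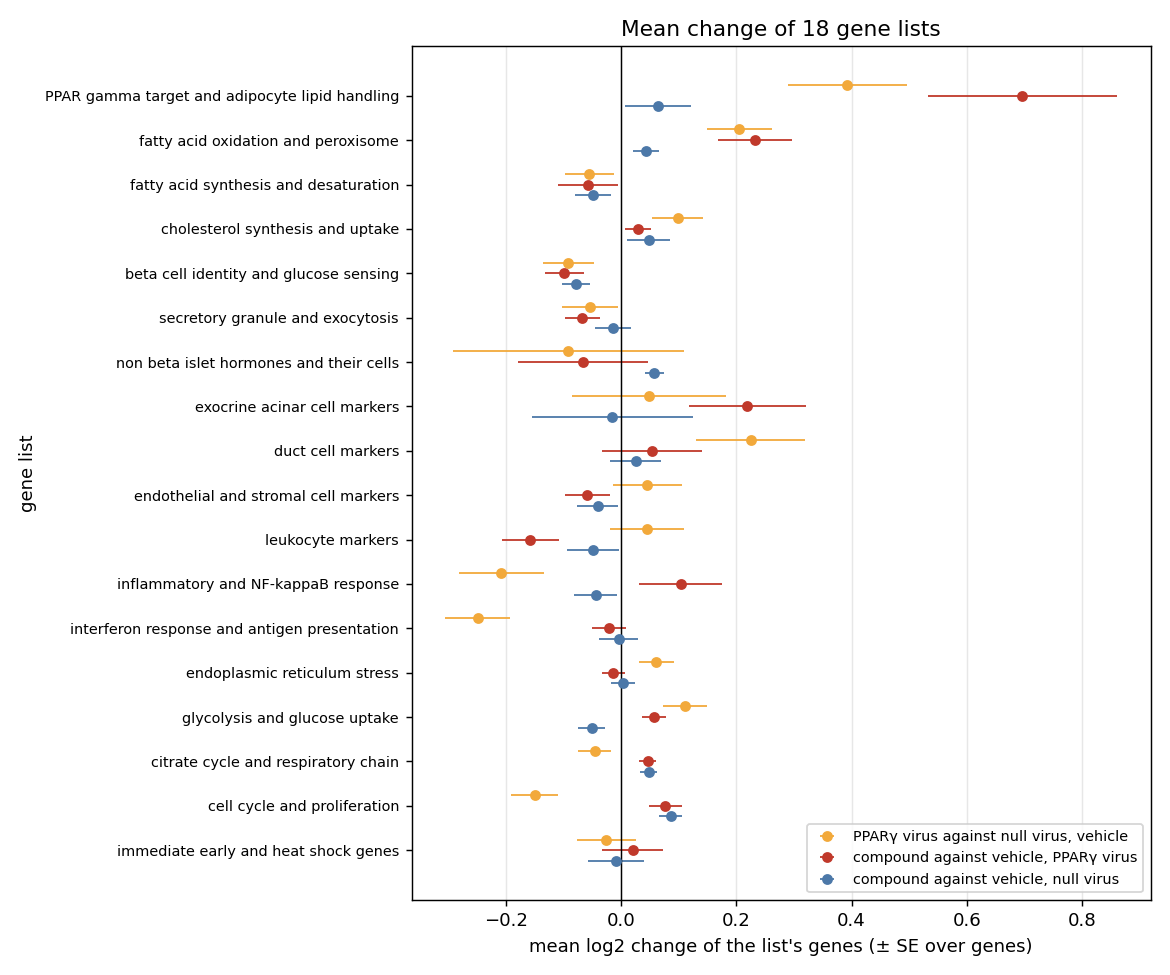
Mean log2 change of the 18 gene lists (horizontal axis) in the virus contrast in vehicle and the compound contrasts under the PPARγ virus and under the null virus. Bars are 1 SE over the genes of a list, which are not independent replicates. In this order, PPARγ targets stood at 0.39, 0.70 and 0.06 and fatty acid oxidation genes at 0.20, 0.23 and 0.04.

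The combined count was 39, 43 or 44 without null virus vehicle replicate 1, 3 or 4, 42 without PPARγ virus compound replicate 4, and 42 when fitted on the groups compared alone. A replicate block over all groups, although not every number paired arrays across viruses, gave 177 (128 up, 49 down). It leaves out that vehicle and compound arrays of the same virus and number deviated together, so its calls may be too many. Among named falls, Calml4 was lost without null vehicle replicate 3 (adjusted p = 0.0566). Psmb9 was lost without null vehicle replicate 1, 3 or 4 or PPARγ compound replicate 1, 3 or 4 (to 0.176). Stard3nl was lost without null vehicle replicate 1 or 3 or PPARγ compound replicate 1 or 4 (to 0.133) and Bclaf1 without null vehicle replicate 1, 3 or 4 or PPARγ compound replicate 3 or 4 (to 0.138). Actr10 was lost without null vehicle replicate 1, 3 or 4, null compound replicate 3, PPARγ vehicle replicate 3 or PPARγ compound replicate 1, 2 or 3 (to 0.165). Among rises, Elovl5 was lost without null vehicle replicate 1 or 3 or PPARγ compound replicate 1, 3 or 4 (to 0.190). Krt19 was lost without null vehicle replicate 3 or 4, null compound replicate 4, PPARγ vehicle replicate 2 or 4 or PPARγ compound replicate 1, 3 or 4 (to 0.211). The beta cell call ended without null vehicle replicate 4 (0.122) or PPARγ compound replicate 2 (0.497, mean -0.10), and with the replicate block over all groups. The glycolysis call ended without null vehicle replicate 3 or 4 or PPARγ compound replicate 1 or 3 (to 0.0667), and with a stricter filter.

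The virus contrast in compound asked what the receptor does once its agonist is present. Pparg (7.14), Fabp4 (4.10, adjusted p = 6.49e-05), Gpd1 (2.82, adjusted p = 2.09e-05), Angptl4 (2.46), Cd36 (2.36), G0s2 (1.86) and Dgat2 (1.59) rose. So did Aqp7, a glycerol channel gene of adipocytes (1.05, adjusted p = 0.00641), Pdk4, a kinase that restrains pyruvate oxidation (0.83, adjusted p = 0.0389), and Krt19 (1.36, adjusted p = 0.0284), while Psmb9 fell by 0.68 (adjusted p = 0.0417). The naming rule did not cover this contrast, and its genes were picked after their values had been seen. Of PPARγ target genes, 11 of 26 rose over all probe sets and 17 adjusted over the list alone (mean 1.03, camera adjusted p = 4.60e-28, and 4.13e-04 with an estimated correlation). Fatty acid oxidation genes rose by 0.39 on average, 6 of 27 over all probe sets and 11 adjusted over the list alone (camera adjusted p = 1.21e-09, and 0.0185 with an estimated correlation). Interferon response genes had a mean of -0.27 with 1 of 27 falling over all probe sets and 1 adjusted over the list alone (camera adjusted p = 1.90e-04; adjusted p = 0.149 with an estimated correlation). Glycolysis genes had a mean of 0.22 with 0 of 21 passing either way (camera adjusted p = 0.00224; adjusted p = 0.302 with an estimated correlation). Duct markers had a mean of 0.25 with 1 of 9 rising over all probe sets and 2 adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.234 with an estimated correlation).

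The contrast called 71 probe sets, 64 up and 7 down, at 926 with an unadjusted p under 0.05. All 4 probe sets called in vehicle, Pparg among them, were also called here. By chance 0.0254 would be shared if the contrasts were independent, which the deviations by number put in doubt. The 71 called in either contrast had the same sign in both. Across 10078 probe sets, which are not independent replicates, the virus effects in vehicle and in compound correlated at Pearson r = 0.615 (0.583 without Pparg) and Spearman rho = 0.492. They share no array, but arrays of the same virus and number deviated together. With Pparg included, the median r over 36 ways of dividing the numbers was 0.561 between effects from arrays of the same numbers. Between effects from arrays of other numbers it was 0.147 (-0.178 to 0.364). The count was 31 or 39 without null virus compound replicate 3 or 4, 42 or 47 without PPARγ virus compound replicate 1 or 3, and 43 when fitted on the groups compared alone. A replicate block over all groups, although not every number paired arrays across viruses, gave 211 (154 up, 57 down), which may be too many. The duct call ended without null virus compound replicate 3 (adjusted p = 0.110, mean 0.10).

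The interaction asked whether the compound acts differently where the receptor is overexpressed. PPARγ target genes did so as a list: their response to the compound was larger under the PPARγ virus by 0.63 on the log2 scale (camera adjusted p = 2.45e-23, and 9.17e-04 with an estimated correlation). Of 26 members, 0 passed over all probe sets and 5 passed adjusted over the list alone, Fabp4 (2.81 ± 0.55), Cd36 (1.91), G0s2 (1.08 ± 0.25), Aqp7 (0.90 ± 0.23) and Acsl1 (0.78 ± 0.18). With the replicate block within each virus, 2 passed over all probe sets and 14 adjusted over the list alone (camera adjusted p = 2.81e-20, and 0.00302 with an estimated correlation). Fatty acid oxidation genes had a mean difference of 0.19, with 0 of 27 passing either way (camera adjusted p = 2.01e-04, but adjusted p = 0.193 with an estimated correlation). The list did not pass the rotation test fry either (adjusted p = 0.752). With the block, 0 passed over all probe sets and 3 adjusted over the list alone (camera adjusted p = 8.78e-05, 0.0380 with an estimated correlation and 0.0413 with fry). The block also gave 1 acinar and 1 inflammatory gene above 0 adjusted over the list alone, in lists that did not pass.

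Limma called 0 single probe sets in the interaction, with 143 at an unadjusted p under 0.05, where chance alone gives 503.9. The largest differences by p, none of which passed, also included Xylt2 (0.80) on the rising side. On the falling side were Mindy1 (-0.95), Anks4b (-0.79), Sart3 (-0.70), Tbca (-0.35) and Dkc1 (-0.92). With the replicate block within each virus, 5 probe sets passed, all upward, and are given although the naming rule covered calls without the block alone. They were Fabp4 (2.81, adjusted p = 0.00104), G0s2 (1.08, adjusted p = 0.00464), a probe set that names no gene (1.78, adjusted p = 0.0303), the growth factor binding protein gene Igfbp1 (1.48, adjusted p = 0.0368) and Gsta4 (1.96, adjusted p = 0.0374). The compound effects under the null and under the PPARγ virus correlated at r = 0.0790 (rho = 0.0591) across probe sets.

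**Figure D3:**
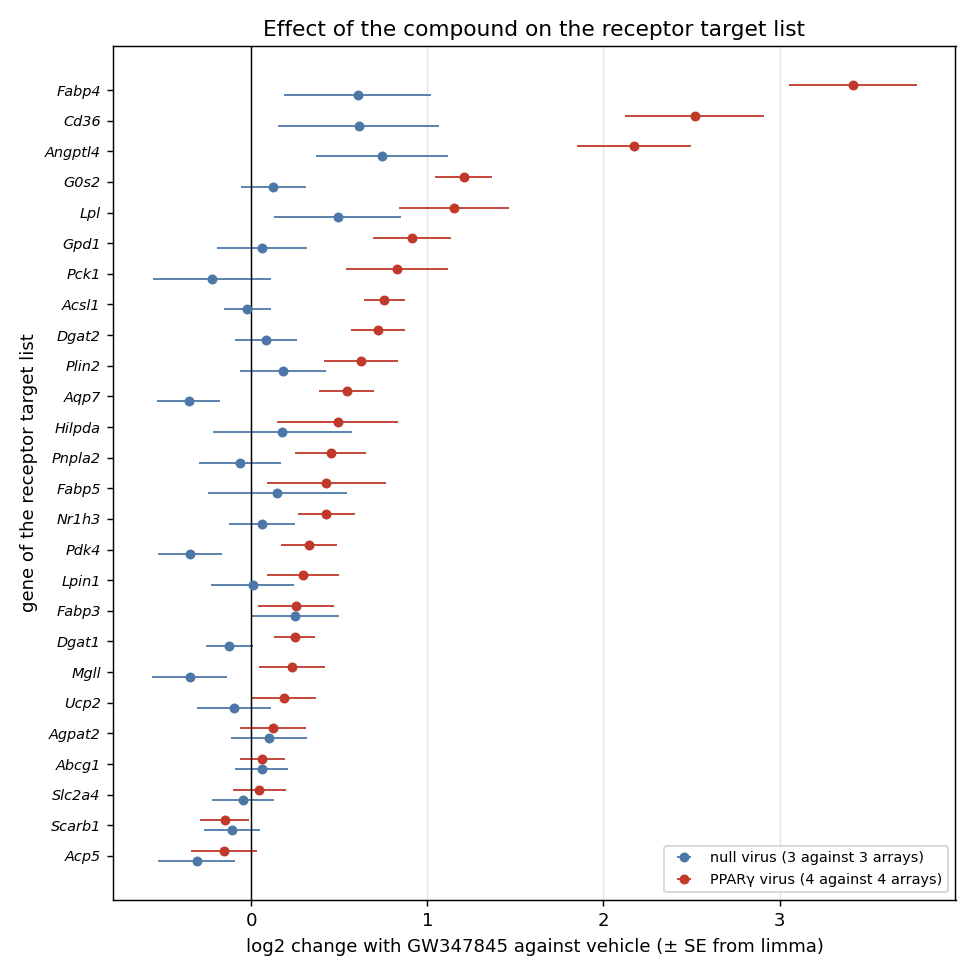
Log2 change with compound of the 26 PPARγ target genes under the null virus and under the PPARγ virus; points are fitted changes and bars 1 SE. The list's mean was 0.06 under the null virus and 0.70 under the PPARγ virus, with Fabp4 at 0.60 and 3.42.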

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

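The tests of scaling, of missing compound, of receptor abundance, of the beta-actin ratio and of non-beta cells were chosen after the results they bear on had been seen.

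The response to the compound differed between viruses. For the PPARγ target list the difference was 0.63 on the log2 scale, and with the replicate block within each virus the differences of Fabp4 (2.81), G0s2 (1.08), a probe set that names no gene (1.78), Igfbp1 (1.48) and Gsta4 (1.96) passed the interaction test. The smaller number of null virus arrays is argued against: with 3 pairs on each side and the block, calls under the PPARγ virus exceeded those under the null virus by 21. Whether the null virus compound arrays hold compound-treated RNA stays open, since the target list changed by 0.0639 (SE 0.0614) over 3 pairs there, and an array was deposited under both null virus labels. More receptor in cells given the PPARγ virus stays open too: the list's interaction (adjusted p = 0.00901 by the rotation test) is the difference itself, which any cause of it would give.

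Calls rose more often than they fell: 91.0% in the combined contrast and 90.1% in the virus contrast in compound. The balance was less one-sided with a replicate block over all groups, at 72.3% and 73.0%, but the calls of that fit may be too many. The authors' scaling of the arrays is argued against, since under quantile normalization or median centring at least 90.9% of calls still rose. Noise in dim probe sets is argued against as well, since at least 86.5% rose among tested probe sets above the median intensity. The filter of at least 4 arrays could be met by a PPARγ virus group alone, but not by a null virus group of 3. Cd36, Ehhadh and Igf1 averaged above 39.3 only in PPARγ virus compound. How far this raised the share of rises is not given here. A biological reading, that the receptor mostly raises its targets, may apply, and no further test of it was run.

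Arrays of the same virus and number deviated together, with a median correlation of 0.574 over 7 pairs. A share of non-beta islet cells that differs between numbers is argued against under the null virus, where 3 pairs kept a median of 0.449 (0.417 to 0.466) after regression on the score of 10 hormone list genes; under the PPARγ virus it may contribute and stays open, with a median of 0.226 over 4 pairs (0.0476 to 0.455) and scores above 0 in numbers 1 and 3 and below 0 in numbers 2 and 4 of either treatment. RNA quality stays open: regression on the Gapdh ratio left a median of 0.576, but Gapdh alone does not stand for RNA quality, since regression on the beta-actin ratio left 0.383 (0.245 to 0.607). A share of acinar cells may contribute and stays open as well, with a median of 0.326 (-0.0945 to 0.717) after regression on the score of 9 markers. The most abundant genes of these lists, 0 of which are in another list, were Gcg (mean intensity 2635, from 180.8 to 4191.7), Gc (2053, from 1504.5 to 2608.8) and Ppy (1762, from 67.6 to 3919.4) for non-beta cells and Reg3b (131) and Cela1 (118, from 37.5 to 351.1) for acinar cells.

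Only the PPARγ virus groups, with 4 arrays each, were screened for single arrays that lay far from the other 3. They appeared in 0 of 36 groups of list scores and 0 of 12 groups of array quality measures. Among groups of named gene values they appeared in 8 of 88, where chance gives 4.4. In PPARγ virus vehicle these were Stard3nl in replicate 1 (334, others 386.7 to 394.2), Calml4 in replicate 3 (170.3, others 108.9 to 115.1), Cry2 in replicate 3 (61.5, others 39.8 to 42.7) and Tbca in replicate 3 (1746.7, others 1630.5 to 1641). In PPARγ virus compound they were Cry2 in replicate 3 (49.2, others 54.7 to 55.6), Sgk2 in replicate 4 (70.1, others 82.3 to 83.5), Borcs8 in replicate 4 (60.1, others 53.7 to 54.6) and Psmb9 in replicate 2 (162.3, others 122 to 128.4). The null virus groups of 3 arrays were not screened. In null virus compound the Gapdh ratio was 18.9 in replicate 3, against 9.87 and 9.05 in replicates 1 and 4.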

How the results depend on the processing

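The fits with the doubly labelled array, with numbers 1, 3 and 4 alone and with the block within each virus were chosen after the data had been seen. Where a value moved below, the cause was not tested. A replicate block over all groups leaves out that vehicle and compound arrays of the same virus and number deviated together. Its counts for the virus and combined contrasts may therefore be too high. With a replicate block over all groups, calls were 34 for the virus in vehicle (22 up, 12 down), 14 for the compound under the PPARγ virus, 177 combined (128 up, 49 down), 211 for the virus in compound (154 up, 57 down) and 3 for the interaction; the block within each virus gave 40 for the compound under the PPARγ virus and 5 for the interaction. Fits on the groups compared alone, which take the spread from fewer arrays, gave 1, 2, 42 and 43 calls for the virus in vehicle, the compound under the PPARγ virus, the combined contrast and the virus in compound. Array weights gave 7 calls for the virus in vehicle and 107 for the virus in compound, and an adjusted p threshold of 0.1 gave 7 for the virus in vehicle. Numbers 1, 3 and 4 alone gave 3 calls for the compound under the PPARγ virus, and with the block 21 (and 4 for the interaction). Of 23 list calls, 8 held with an estimated correlation and 11 with fry. The concordance of the virus effect (Pearson r) was 0.418 without a filter, 0.711 with a stricter filter, 0.652 with the replicate block, 0.645 with all 16 columns and 0.577 with the doubly labelled array as vehicle; concordance of the compound effect was 0.00102 with this array as vehicle and 0.142 with it as compound.

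Leaving out each array in turn gave 3 to 7 calls for the virus in vehicle, 0 to 0 for the compound under the null virus and for the interaction, 2 to 7 for the compound under the PPARγ virus, 39 to 71 combined, 31 to 71 for the virus in compound, 20 to 32 list calls, and correlations of 0.541 to 0.602 and 0.0145 to 0.114. The change of Pparg was 7.12 to 7.34 over these fits for the virus in vehicle. The compound under the null virus gave 0 limma calls under every alternative run, against 95 at an unadjusted p under 0.05. All 16 columns as designed gave 4 calls for the virus in vehicle, 0 for the compound under the null virus, 6 for the compound under the PPARγ virus, 88 combined, 100 for the virus in compound and 0 for the interaction. Among named genes, median centring ended the combined calls of Psmb9, Actr10, Stard3nl and Elovl5, and all 16 columns ended those of Actr10, Stard3nl, Bclaf1 and Krt19 and that of G0s2 with compound under the PPARγ virus. Of the list calls and of the genes named by the rule, which were followed through the alternatives, no result that passed its test reversed direction, except that the mean of the citrate cycle list turned to -0.01, its call lost, without PPARγ virus compound replicate 4. Pparg, Fabp4, Cd36, Plek, Ehhadh, Gsta4, Igf1, Sgk2, Aqp7, Fga and Sec31a averaged below 39.3 with the null virus, so their fold changes depend on the pseudocount. A pseudocount of 1 ended the call of Cd36 with compound under the PPARγ virus.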

Other observations

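The genes of the next paragraph were chosen after their values had been seen, and the split counts were planned.

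The 7 genes given here lie outside the gene lists, and no theme was tested on them. The microsomal glutathione transferase gene Mgst1 averaged 282, 348, 467 and 909 intensity in null vehicle, null compound, PPARγ vehicle and PPARγ compound arrays, and rose by 1.69 on the log2 scale in the combined contrast (adjusted p = 9.30e-04). Gsta4 averaged 29.9, 32.2, 93.8 and 422 in the same order. Igfbp1, a binding protein of insulin-like growth factors, averaged 45.5, 34.2, 98.0 and 211 (1.98, adjusted p = 0.0306). Ang, the gene of the ribonuclease angiogenin rose by 2.38 (adjusted p = 0.00284). The hydrogen peroxide-forming oxidase gene Duox2 rose by 1.80 (adjusted p = 0.0418), the transglutaminase gene Tgm2 by 1.66 (adjusted p = 0.0295) and the heparan sulfate sulfotransferase gene Hs3st1 by 1.81 (adjusted p = 0.00901).

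Other splits of the same arrays were counted. For the virus in vehicle, 1 of 35 splits, the real one, gave as many as its 4 calls, the highest other giving 1; for the combined contrast 1 of 35 gave 67, the highest other giving 1; for the virus in compound 1 of 35 gave 71, the highest other giving 0. Pparg, which the virus itself carries, is among the calls of each real split, and 1 of 35 is the smallest share possible. The splits treat arrays as exchangeable, which their structure by number puts in doubt. Chance is therefore argued against for these counts but not excluded. For the compound under the PPARγ virus, 2 of 35 splits gave at least the real 6 calls, so chance is not excluded for this count without the block; the other was numbers 1 and 3 against 2 and 4, which parts no pair and gave 1808 calls, which points to a structure of the arrays by number whose source the labels do not give. Of the 7 other splits that part all 4 pairs, as the real one does, the highest gave 0. With the block, the real split gave 40 and the highest of the other 7 gave 0, but 8 splits are too few for a share under 0.05; the same holds for the compound under the null virus, with 10 splits that all gave 0 like the real one. For the interaction, 100 of 100 splits gave at least the real 0, the highest giving 719.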
